A study of Arundo donax with 6 samples.

How the data were processed

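Leaf RNA from 6 samples of 1 genotype was analysed, 3 controls and 3 irrigated with 250 mM NaCl. Per the labels' protocols, RNA was extracted with a column kit, messenger RNA was enriched with oligo(dT) beads and fragmented, and cDNA was made from random hexamers. The submitters' processing notes name CASAVA 1.8, RSEM and DESeq. The assembler, the mapping settings and the role of each tool are not given in the sources used here. No reference genome was used, so no coordinates are given. The design text calls the samples biological replicates.

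The deposited files give, per unigene, an expected count (an estimated read count that need not be whole) and an FPKM, both made by the authors, per the file headers. Between 61.5% and 63.2% of the counts were not whole. The deposited FPKM values had a minimum of 0.31 in each library and no value of 0. The files thus appear cut at an FPKM of about 0.3, and an absent unigene can still hold reads. At that limit, the median count of absent unigenes would be 2.03 to 3.40 by library. Absent unigenes were taken as a count of 0, and an alternative set them at that limit. Reads shared between gene copies are divided by estimation in expected counts. Also, 90.4% of unigenes share 1 cluster number, so values of near-identical copies are uncertain. The protocol as labelled marks no strand.

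Counts were rounded to whole numbers, filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were taken as the log2 difference divided by the square root of F. DESeq2 1.42.0 and limma 3.58.1 were alternatives, the latter on log2(FPKM + 1) or log2(FPKM + 0.1). CPM values are scaled by TMM, and salt replicate 3 beside 5-library values was scaled with all 6 libraries. The 23 gene lists, matched by words in protein descriptions, comprised 18 of function, 3 of cell type markers and 2 of control genes, and were fixed before the data were examined, as were the design and the rule for naming genes. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The pattern for late embryogenesis proteins also matched phloem proteins by chance, and a narrowed pattern kept 9 of 11 entries and the same 3 calls.

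The rule for named genes took the 4 largest and 4 smallest changes among called plant genes of named function with groups that do not overlap and an average log2 CPM at or above the median of those tested. For each list of function it added the most abundant called member in each direction, or the 2 most abundant where only 1 direction had calls. Where a list had no call it took the most abundant member, as values. Tests on 5 libraries with counts summed per Swiss-Prot entry were added after the data were examined, and the same rule was applied there to both salt libraries kept. The search for these tests held 10 further settings, which stand among the alternatives with DESeq2, limma, other scalings and filters, a replicate block, a batch term and each library left out.

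Enrichment used 1-sided Fisher's exact tests over terms of 10 to 500 entries, with the 11248 tested entries that carry a term as background. The planned enrichment, over unigenes called by edgeR, had 0 calls to work on, and it was not run on the unigenes called by DESeq2. The non-plant share used an exact permutation test. Matches to spider mites, aphids and a lancelet were taken from the nucleotide annotation at an E-value under 1e-20. The tests were tried on simulated counts with 200 changed features. In 5 libraries of entries, 85.1% of 67 entries changed 2-fold and 100% of those changed 4-fold were recovered, with 12 of the unchanged called. In 6 libraries of unigenes 0% were recovered at each fold. The simulated spread came from the fitted trend alone, the same for each library and for features of like abundance. Recovery in the real libraries can therefore differ, and that in 5 libraries may be overstated. Python 3.11.15, scipy 1.17.1 and statsmodels 0.14.6 were used.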

Results

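Leaf RNA of giant reed (Arundo donax), a perennial grass grown for biomass, was sequenced from the genotype G34 in 2 groups of 3 biological replicates each. Control plants were irrigated weekly with water, and salt plants with water holding 250 mM NaCl. Reads were assigned to 240288 unigenes, the assembled transcript sequences that stand in for genes where no reference genome is used. Total estimated counts per library were 23644652, 21967119 and 21962800 in controls 1 to 3 and 24947396, 24035259 and 23912187 in salts 1 to 3. Of the unigenes, 96618 carried a best match among 16003 Swiss-Prot protein entries, whose names are used for genes below. An entry name is that of the closest catalogued protein, often from another plant, and 1 entry can pool several gene copies.

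The libraries differed in how alike they were. Across unigenes, pairs of libraries without salt replicate 3 had Pearson correlations of 0.80 to 0.96, and pairs with it 0.36 to 0.45. Across Swiss-Prot entries the ranges were 0.89 to 0.99 and 0.60 to 0.67. These correlations are across genes, which are not independent replicates. Salt replicate 3 listed 90248 unigenes, against 161679 to 169017 in the others, at a like depth. Of 29428 unigenes with at least 100 counts in each other library, 9172 were absent from salt replicate 3.

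**Figure D1:**
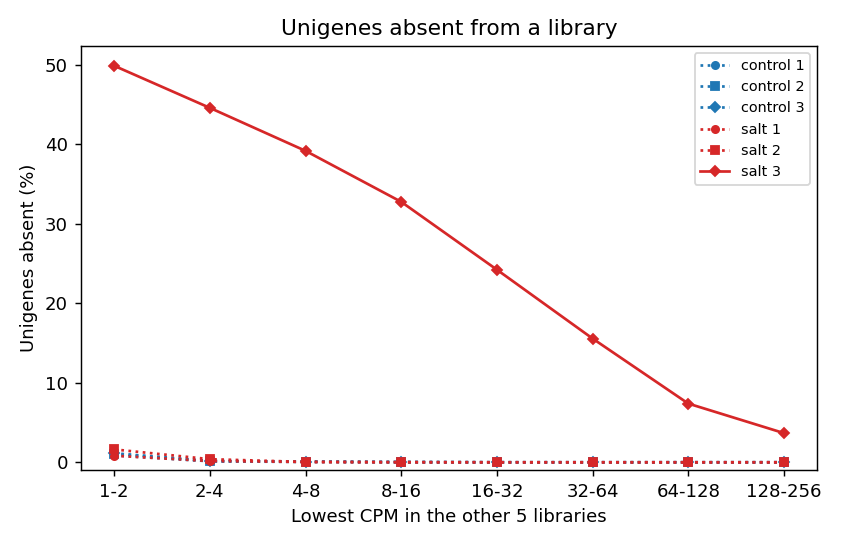
Percent of unigenes absent from a library (vertical axis) by their lowest CPM in the other 5 libraries (horizontal axis, ranges of CPM), with controls in blue and salt libraries in red. The solid line is salt 3, which lacked 49.9% of unigenes at 1 to 2 CPM and 24.2% at 16 to 32 CPM.

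The comparison of salt with control asked which leaf transcripts change in this genotype under 250 mM NaCl. With edgeR no unigene was called, while DESeq2 called 860 higher and 976 lower, so values are given for the most abundant unigene of each of the 18 functional lists. A unigene of dehydrin HIRD11, a protein of the dehydrin family linked to water loss, stood at 75.6 ± 8.69 CPM in controls and 235 ± 62.6 in salt (SD, n = 3 each). Its log2 difference was 1.64 ± 0.29 (SE), with an edgeR adjusted p of 0.551. A unigene of the plasma membrane proton pump (Plasma membrane ATPase) stood at 275 ± 11.1 and 407 ± 137 CPM. One of NAC domain-containing protein 48, a transcription factor, stood at 210 ± 2.94 and 370 ± 173 CPM. One of Probable WRKY transcription factor 46 stood at 31.4 ± 3.35 and 229 ± 250 CPM, with 27.0, 152 and 509 CPM in the salt libraries. For Catalase-1, which breaks down hydrogen peroxide, the values were 1618 ± 229 and 2042 ± 1067 CPM. For Heat shock protein 81-1 they were 525 ± 44.4 and 545 ± 9.45 CPM. The rubisco activase unigene stood at 998 ± 45.0 and 1198 ± 403 CPM, and the Oxygen-evolving enhancer protein 1 unigene at 1443 ± 41.7 and 1621 ± 780 CPM. Higher means in salt were also seen for Probable galactinol--sucrose galactosyltransferase 2 (297 ± 86.2 and 806 ± 582 CPM), the Glycine-rich RNA-binding, abscisic acid-inducible protein (424 ± 26.7 and 835 ± 412), Protein ETHYLENE INSENSITIVE 3 (215 ± 24.0 and 314 ± 197), Phosphoenolpyruvate carboxylase 1 (157 ± 11.3 and 215 ± 158), Flavonoid 3'-monooxygenase (130 ± 16.5 and 327 ± 225) and Aquaporin TIP4-2 (206 ± 22.1 and 372 ± 262). Lower means in salt were seen for Betaine aldehyde dehydrogenase 2 (141 ± 11.9 and 110 ± 85.4 CPM), the Jasmonate-induced protein homolog (216 ± 26.5 and 77.4 ± 80.8), the cysteine protease SAG39 (638 ± 89.4 and 517 ± 250) and Cellulose synthase-like protein E6 (498 ± 62.7 and 404 ± 178). Without salt replicate 3 the sign turned for 6 of the 18, Catalase-1, Oxygen-evolving enhancer protein 1, Phosphoenolpyruvate carboxylase 1, ETHYLENE INSENSITIVE 3, Betaine aldehyde dehydrogenase 2 and Cellulose synthase-like protein E6.

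With all 6 libraries, edgeR's quasi-likelihood test called 0 of 114765 unigenes at a Benjamini-Hochberg adjusted p under 0.05. At an unadjusted p under 0.05 there were 4977 unigenes, 3484 higher and 1493 lower in salt. On log2(FPKM + 1) limma called 0, with 3710 higher and 3912 lower at that level, and on log2(FPKM + 0.1) 8 higher and 19 lower. Without salt replicate 3, edgeR again called 0, with 10933 higher and 10202 lower at an unadjusted p under 0.05, and without salt replicate 2 it called 0, with 2558 and 2565. In counts simulated at the spread fitted over these 6 libraries, set equal in every library, the edgeR test recovered 0% of unigenes changed 16-fold. The real libraries were not equally spread, with salt replicate 3 apart, so real recovery can differ.

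Gene lists were tested with camera on the same 6 libraries. At the preset correlation, 13 of 23 lists were called higher in salt relative to other unigenes, led by the WRKY, jasmonate and phenylpropanoid lists (adjusted p = 1.02e-19, 7.77e-17 and 8.67e-13). Lists of cell type markers were among the 13, epidermis and cuticle (adjusted p = 3.42e-07) and vascular tissue (adjusted p = 0.00115). With an estimated correlation none was called, and the lowest adjusted p was 0.0575. Without salt replicate 3, 5 of the 13 stayed (WRKY, jasmonate, phenylpropanoid, cell wall and dehydrins). Ion transport, reference genes and ribosomal proteins were then called higher too, and light reactions and Calvin cycle lower (adjusted p = 2.14e-08 and 2.22e-06), none of them with an estimated correlation (lowest adjusted p = 0.499). Without salt replicate 2 the light reactions list was called higher instead (adjusted p = 0.00269), and not with an estimated correlation (adjusted p = 0.403). Without salt replicate 1, 6 lists were called higher with an estimated correlation, with the lowest adjusted p for WRKY (0.0235). The jasmonate list had a median log2 difference of 0.87 over 142 unigenes and the WRKY list 0.88 over 268.

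A further comparison left out salt replicate 3 and summed counts per Swiss-Prot entry. It was chosen after the data had been seen and after the planned edgeR test had called no unigene, so its calls are exploratory. Controls are n = 3 and salt replicates 1 and 2 are n = 2, with SD. Named here are the largest called changes among entries of at least median abundance whose groups did not overlap. The largest increase among these was in Glucan endo-1,3-beta-glucosidase (P49237), an enzyme that cuts a cell wall glucan, from 6.64 ± 1.70 to 193 ± 229 CPM. Its salt libraries stood at 31.4 and 355 CPM. S-type anion channel SLAH2 (Q9ASQ7) rose from 7.62 ± 1.52 to 76.9 ± 19.6 CPM, a log2 difference of 3.33 ± 0.23 (SE, edgeR adjusted p = 0.0205). Protein PIN-LIKES 7 (Q9FKY4) rose from 19.5 ± 3.29 to 207 ± 165 CPM, with 89.8 and 324 CPM in salts 1 and 2. Serine carboxypeptidase 2 (P08818) rose from 26.8 ± 9.82 to 239 ± 138 CPM, with 141 and 336 CPM in salts 1 and 2. The largest decrease among these was in Transcription factor bHLH100 (Q9ZVB5), a regulator of iron deficiency responses in Arabidopsis, which fell from 154 ± 7.14 to 2.05 ± 2.30 CPM. Its log2 difference was -6.20 ± 0.76 (edgeR adjusted p = 0.0344). Phosphate transporter PHO1-1 (Q657S5) fell from 78.6 ± 18.7 to 11.7 ± 1.28 CPM and Protein RADIALIS-like 3 (Q6NNN0) from 75.9 ± 7.40 to 15.3 ± 7.17 CPM. A RuBisCO large subunit-binding protein subunit alpha entry (P08926) fell from 69.8 ± 34.8 CPM, with 29.9 CPM in control 1, to 4.22 and 4.19 CPM in the salt libraries. That entry rests on 1 unigene. A more abundant entry of the same subunit (P08823), with 6 unigenes, fell less, from 768 ± 39.5 to 473 ± 67.8 CPM. In salt replicate 3, bHLH100 stood at 32.8 CPM, SLAH2 at 194 CPM and the chaperonin entry P08926 at 94.0 CPM.

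In these 5 libraries, edgeR called 565 of 13963 entries higher and 636 lower in salt at an adjusted p under 0.05, with 4383 at an unadjusted p under 0.05, and 0 at an adjusted p under 0.01. DESeq2 called 1567 higher and 1425 lower. Of 26 edgeR fits over unigenes, or over entries with all 6 libraries, 1 made calls, with 691 unigenes higher and 590 lower. Calls by edgeR were 0 higher and 1 lower without control replicate 1 and 0 without control replicate 2 or 3 (2967, 3174 and 3037 at an unadjusted p under 0.05), 2533 higher and 2120 lower without salt replicate 1, and 293 and 318 without salt replicate 2. They were 0 with all 6 libraries, with a replicate block and with a term for a possible technical batch (1415, 3475 and 1919 at an unadjusted p under 0.05). The fit with the batch term sets the single control library of that batch against salts 1 and 2, and there all 565 and 636 entries kept their direction and 540 and 630 an unadjusted p under 0.05, with the same libraries in both fits.

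Gene lists were counted in the same exploratory comparison. Among 94 entries of ion transport, 18 rose and 3 fell (31 and 9 adjusted over the list alone). Most of those that rose were subunits of the V-type proton ATPase, the pump that acidifies the vacuole. Its catalytic subunit A (P09469) rose from 497 ± 4.34 to 751 ± 70.7 CPM. Sodium/hydrogen exchanger 2 (Q56XP4) fell from 236 ± 7.29 to 164 ± 19.4 CPM. In salt replicate 3 the catalytic subunit stood at 114 CPM and the list's median log2 ratio to controls was -0.41, against 0.18 and 0.31 in salts 1 and 2. Camera called the list higher (adjusted p = 0.00928), and not with an estimated correlation (adjusted p = 0.646).

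Of 72 light reaction entries 0 rose and 7 fell (1 and 22 adjusted over the list alone), and of 34 Calvin cycle entries 0 rose and 6 fell (1 and 13 adjusted over the list alone). Oxygen-evolving enhancer protein 3-1 (Q41048), part of photosystem II, fell from 929 ± 84.1 to 536 ± 87.0 CPM. Photosystem I subunit psaK (P36886) fell from 772 ± 93.8 to 429 ± 87.1 CPM. The called Calvin cycle members included a rubisco small chain, an activase, a methyltransferase of aldolase and RuBisCO large subunit-binding proteins, which are chaperonins. The subunit beta entry (Q43831) fell from 1883 ± 138 to 1075 ± 176 CPM. Camera called both lists lower (adjusted p = 7.01e-07 and 8.63e-05), and neither with an estimated correlation (adjusted p = 0.646 for both). In salt replicate 3 the light reaction list lay on the other side, with a median log2 ratio of 0.95 against -0.19 and -0.61 in salts 1 and 2. Oxygen-evolving enhancer protein 3-1 stood at 2933 CPM there, and the Calvin cycle list had a median of -0.95 there.

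Of 41 jasmonate entries, 7 rose and 1 fell (9 and 1 adjusted over the list alone). Those that rose included linoleate 9S-lipoxygenases (P29250, Q53RB0 and Q7G794), matched by the word lipoxygenase, which alone does not show a role in jasmonate synthesis. Allene oxide synthase 2 (Q7XYS3) rose from 1.61 ± 1.14 to 51.2 ± 55.2 CPM, with 12.2 and 90.2 CPM in salts 1 and 2. Rises were also called for 12-oxophytodienoate reductase 1 (Q84QK0, 16.3 ± 1.35 to 39.6 ± 8.19 CPM) and Probable lipoxygenase 8 (Q84YK8, 16.3 ± 2.37 to 40.8 ± 16.7 CPM). Jasmonic acid-amido synthetase JAR2 (Q5NAZ7), which forms the active hormone conjugate, rose from 166 ± 2.42 to 241 ± 32.3 CPM. Jasmonate O-methyltransferase (Q9SBK6) fell from 8.03 ± 1.01 to 3.82 ± 0.84 CPM. The list's median log2 ratio was 0.21 in salt replicate 1, 1.45 in salt replicate 2 and 2.42 in salt replicate 3, and salt replicate 2 also held spider mite RNA at 231 CPM. Of 45 WRKY transcription factor entries 6 rose and 0 fell (14 and 1 adjusted over the list alone), with medians of 0.12, 0.92 and 2.39 in the salt libraries. WRKY transcription factor 6 (Q9C519) rose from 192 ± 17.3 to 422 ± 85.7 CPM. Camera called both lists higher (adjusted p = 0.000617 and 0.0127), and neither with an estimated correlation (adjusted p = 0.646 and 0.65). Without salt replicate 2 the WRKY call ended (adjusted p = 0.483).

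**Figure D2:**
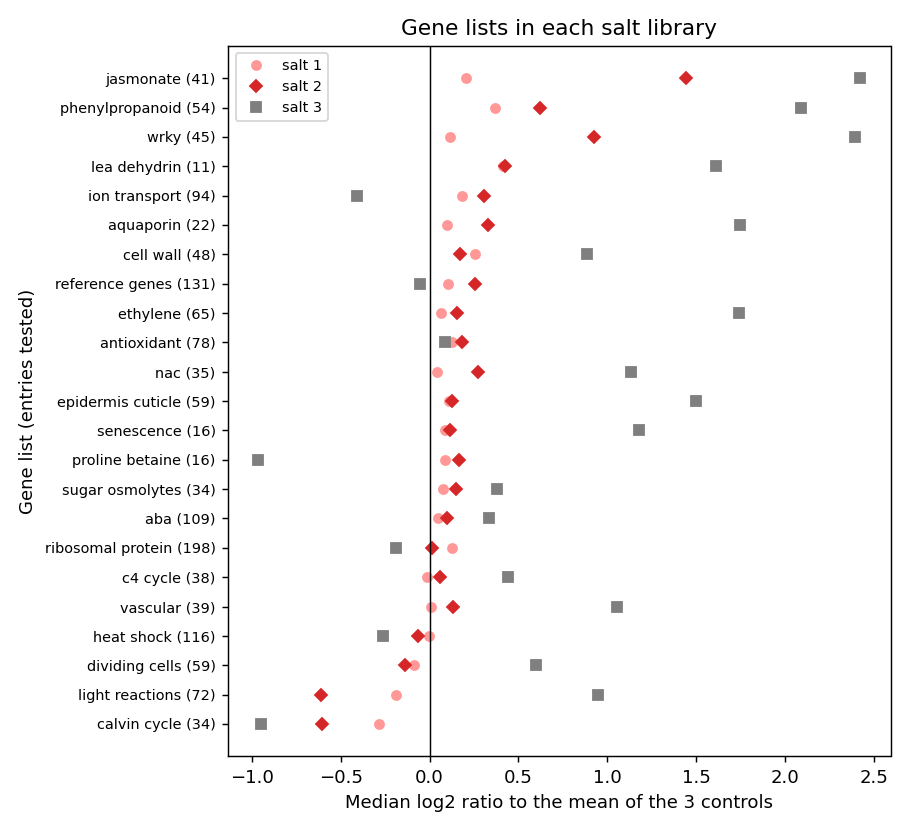
Median log2 ratio of each salt library to the mean of the 3 controls (horizontal axis) for each gene list (vertical axis, with the number of entries tested). Salt 3 lay opposite to salts 1 and 2 for light reactions (0.95 against -0.19 and -0.61) and for ion transport (-0.41 against 0.18 and 0.31).

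Among 11 entries matched as late embryogenesis abundant proteins and dehydrins, 3 rose and 0 fell (3 and 0 adjusted over the list alone). Dehydrin HIRD11 (Q9SLJ2) rose from 142 ± 15.9 to 328 ± 125 CPM and Dehydrin COR410 (P46524) from 254 ± 13.0 to 390 ± 67.8 CPM. They stood at 568 and 828 CPM in salt replicate 3. Of 16 proline and betaine entries, 1 rose and 1 fell (1 and 1 adjusted over the list alone). Proline dehydrogenase 2 (Q6NKX1), the first enzyme of proline breakdown, fell from 257 ± 16.6 to 138 ± 16.7 CPM and stood at 754 CPM in salt replicate 3. Delta-1-pyrroline-5-carboxylate dehydrogenase (Q8VZC3), which follows it, rose from 72.6 ± 7.24 to 109 ± 0.74 CPM and stood at 35.2 CPM in salt replicate 3. That list had a median log2 ratio of -0.96 in salt replicate 3, against 0.09 and 0.17 in salts 1 and 2. Of 34 sugar osmolyte entries 1 rose and 1 fell (2 and 1 adjusted over the list alone). Galactinol synthase 1 (O22893), of raffinose synthesis, rose from 70.6 ± 7.33 to 111 ± 4.24 CPM, and Probable sucrose-phosphate synthase 3 (Q67WN8) fell from 43.3 ± 2.06 to 30.8 ± 2.37 CPM. In salt replicate 3 they stood at 440.2 and 0 CPM.

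Of 78 antioxidant entries, 9 rose and 6 fell (21 and 13 adjusted over the list alone). Cytosolic glutathione reductase (P48642) rose from 340 ± 18.5 to 522 ± 1.48 CPM, and the chloroplast 2-Cys peroxiredoxin BAS1 (Q6ER94) fell from 682 ± 34.7 to 439 ± 43.5 CPM. Salt replicate 3 held them at 187 and 782 CPM, on the other side of the controls. Of 38 entries of carbon fixation through phosphoenolpyruvate, 4 rose and 3 fell (5 and 4 adjusted over the list alone). Most of those that rose were phosphoenolpyruvate carboxykinases, matched by name, which alone does not show a role in carbon fixation. One of them (Q9SLZ0) rose from 208 ± 25.2 to 983 ± 650 CPM. Beta carbonic anhydrase 5 (Q94CE3) fell from 209 ± 19.8 to 136 ± 17.4 CPM. Both Phosphoenolpyruvate carboxylase kinases of the list fell. The median log2 difference of this list was -0.01, its mean 0.11 and its camera direction up. Of 65 ethylene entries 3 rose and 0 fell (2 and 0 adjusted over the list alone), all 3 of them oxidases that make ethylene. One of these (A2Z1W9) rose from 37.6 ± 1.93 to 85.7 ± 10.3 CPM. Of 109 abscisic acid entries 4 rose and 5 fell (2 and 4 adjusted over the list alone). Among them were Probable protein phosphatase 2C 72 (Q7XCJ7), higher 1.57-fold, and 2C 50 (Q6L5H6), lower 1.44-fold. Most of those called were matched by the family name protein phosphatase 2C, which alone does not show a role in abscisic acid signalling.

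Of 54 phenylpropanoid entries 4 rose and 2 fell (7 and 4 adjusted over the list alone). Trans-cinnamate 4-monooxygenase (Q96423) rose from 114 ± 5.11 to 187 ± 32.7 CPM. Camera called this list higher (adjusted p = 0.00584), and neither with an estimated correlation (adjusted p = 0.646) nor without salt replicate 2 (adjusted p = 0.0786). Of 48 cell wall entries 6 rose and 0 fell (11 and 1 adjusted over the list alone), among them Probable cellulose synthase A catalytic subunit 1 (A2Y0X2), from 36.6 ± 1.27 to 80.0 ± 17.7 CPM, with 0.685 CPM in salt replicate 3. Of 116 heat shock entries 1 rose and 4 fell (1 and 2 adjusted over the list alone). Heat shock 70 kDa protein 17 (F4JMJ1) rose from 83.4 ± 5.53 to 161 ± 14.3 CPM, with 69.4 CPM in salt replicate 3, and all 4 entries that fell were heat stress transcription factors. Of 16 senescence entries 1 rose and 0 fell (1 and 0 adjusted over the list alone), and of 22 aquaporin entries 0 rose and 1 fell (0 and 1 adjusted over the list alone). None of 35 NAC entries was called by edgeR, over all entries or adjusted over the list alone, and NAC domain-containing protein 48 (Q7F2L3) stood at 624 ± 20.9 and 814 ± 22.3 CPM (adjusted p = 0.0702).

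**Figure D3:**
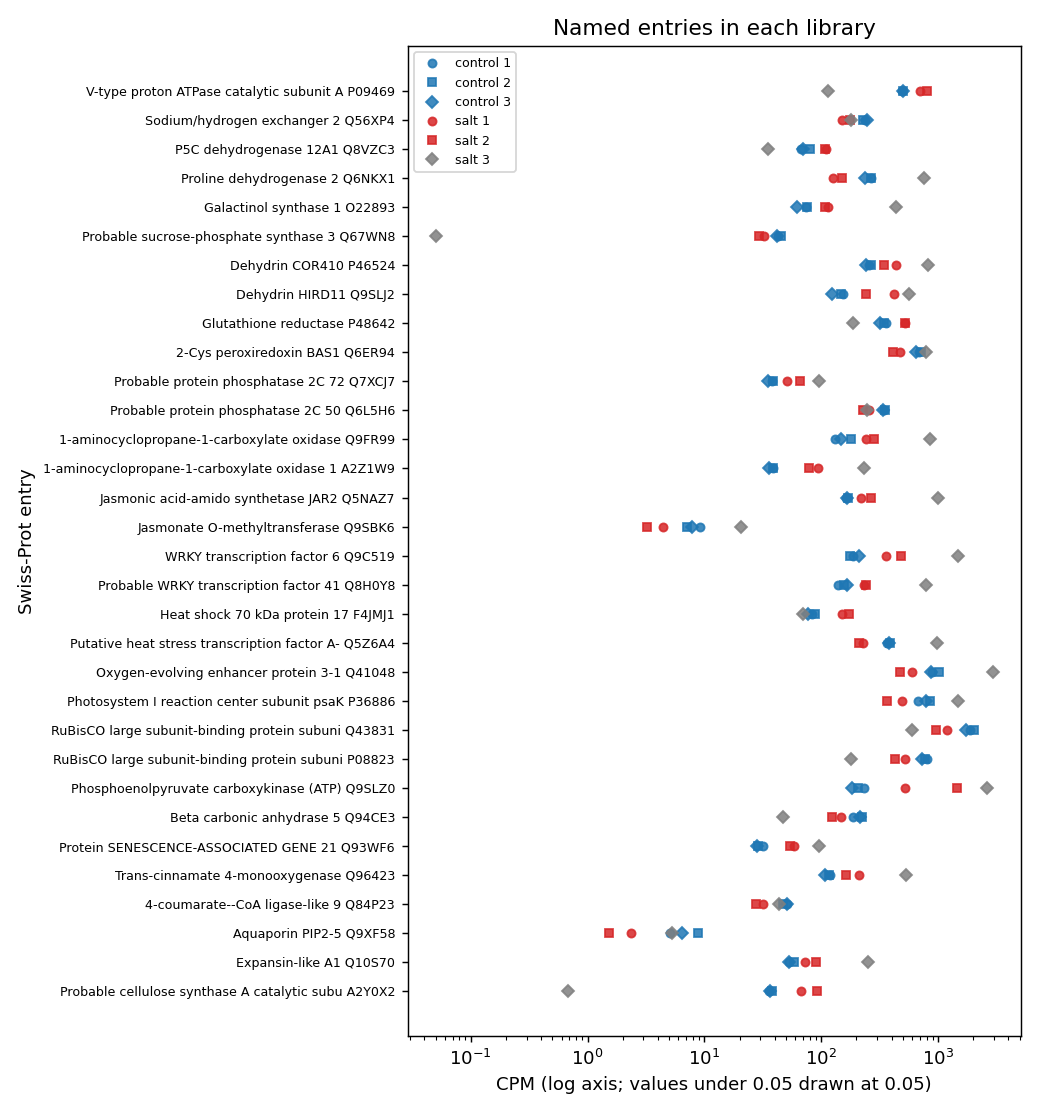
CPM in each library (horizontal log axis) of the called members that the naming rule took from the lists of function, at most 2 per list. Controls are in blue, salts 1 and 2 in red and salt 3 in grey. Phosphoenolpyruvate carboxykinase stood at 524 and 1443 CPM in salts 1 and 2, above the controls, and Oxygen-evolving enhancer protein 3-1 at 597 and 474 CPM, below them.

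Lists of markers of other cell types and of reference genes were counted in the same fit. Of 59 entries of dividing cells 0 rose and 1 fell, of 59 of epidermis and cuticle 3 rose and 4 fell, and of 39 of vascular tissue 5 rose and 3 fell (0 and 0, 6 and 5, and 5 and 3 adjusted over the list alone). In salt replicate 3 the median log2 ratios were 0.60 for dividing cells, 1.05 for vascular tissue and above both for epidermis, against -0.14 to 0.13 in salts 1 and 2. The vascular median was -0.02 and its mean 0.21. In these 5 libraries none of these lists was called by camera (adjusted p = 0.215, 0.406 and 0.816). Of 198 ribosomal protein entries edgeR called 0, over all entries or adjusted over the list alone, with a median log2 difference of 0.05 and a mean of -0.55. Of 131 entries matched by names of commonly used reference genes, 9 rose and 0 fell (8 and 0 adjusted over the list alone). They were polyubiquitins, tubulins and entries matched by the word actin. The latter included Actin-depolymerizing factor 5 (Q10P87) and Actin-related protein 2 (A2YUL5), for which that word alone does not show use as a reference. Camera called this list higher (adjusted p = 0.00928), though not with an estimated correlation (adjusted p = 0.646).

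Gene Ontology process terms were tested among the called entries with Fisher's exact test. Of 671 terms, 4 were called for increases and 2 for decreases. Response to cadmium ion held 26 of the entries that rose, against 7.75 expected (adjusted p = 7.08e-05). Tricarboxylic acid cycle held 13 against 3.40 expected (adjusted p = 0.00958), and ATP hydrolysis coupled proton transport 17 against 5.66 (adjusted p = 0.0127). Cellular carbohydrate metabolic process held 6 of the entries that rose, against 0.479 (adjusted p = 0.0014). RNA modification held 23 of the entries that fell, against 7.82 expected (adjusted p = 0.0014), and chloroplast organization 6 against 0.843 (adjusted p = 0.0263). With entries changed at least 2-fold, 0 terms were called by Fisher's exact test.

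The share of counts on unigenes with a best protein match outside green plants was 0.00781% ± 0.00423 in controls and 0.00686% ± 0.00506 in salt (SD, n = 3 each). The exact permutation p was 0.9, two-sided, where the smallest possible is 0.1. Unigenes without a protein match were counted as plant, so this share misses most of the mite RNA. Salt replicate 2 held 34.5 CPM on animal protein matches and 231 CPM on mite nucleotide matches.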

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

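The tests of carry-over and of the jasmonate list below were chosen after the result was seen. Unigenes matching spider mites stood at 231 CPM in salt replicate 2 and 8.21 CPM in salt replicate 3, against 2.94 to 3.75 CPM in controls. Those matching aphids stood at 56.8 CPM in salt replicate 2, against 0 to 4.78 in controls. Both lie outside the comparison of plant genes and above every control. The same values argue against carry-over shared evenly between libraries, with at least 46.1 CPM of mite RNA in another library, since the highest was 8.21, and say nothing of other carry-over. Feeding may have raised the jasmonate list in salt replicate 2: its median log2 ratio to salt replicate 1 was 1.00 and lay at percentile 100 of 10000 matched random lists, whose central range was -0.15 to 0.16. Only 1 library was infested to this degree, so mites, salt and other differences between these libraries cannot be told apart. The random lists were matched on abundance and do not carry the correlation between members of this list. In salt replicate 3, with less mite RNA, the list's median log2 ratio to controls was higher still, at 2.42 against 1.45 in salt replicate 2.

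Unigenes matching a lancelet, a marine animal, stood at 15.1, 16.9 and 17.8 CPM in salts 1 to 3, and at 0, 0 and 14.3 in controls 1 to 3. All 3 salt libraries lie above every control. These reads may mark a technical batch that holds control 3 and the salt libraries, and the batch test was chosen after the calls were seen. If that batch were behind the 5-library calls, control 3 should lie with the salt libraries. Across 3037 entries at p under 0.05 between the other controls and salts 1 and 2, its median position was 0.0809 on a scale from 0 (those controls) to 1 (those salt libraries). The same measure for controls 1 and 2, each left out in turn, was 0.00846 and 0.0724. With the batch term the called entries had a median log2 difference of 0.88 (higher) and -0.73 (lower), against 0.90 and -0.76 without it, and median SEs of 0.25 and 0.19, against 0.16 and 0.13. The calls thus ended with larger errors at like differences, which is no evidence for a batch. Both values rest on a single control library, so the batch stays open.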

How the results depend on the processing

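Alternatives fixed before the data were examined are named first. For unigenes in 6 libraries, edgeR called 0 under RLE and upper quartile scaling, both filters, the replicate block, each library left out, unigenes in all files, plant unigenes and entry sums, with 1382 to 21135 at an unadjusted p under 0.05. So did the batch term (2209) and absent unigenes set at FPKM 0.3 (12756), both chosen after seeing the data. The plant setting tested 114740 unigenes against 114765, so it could hardly change the result and is no test of non-plant RNA. The median log2 difference moved from -0.27 to -0.15 with upper quartile scaling, 0.02 with unigenes in all files, 0.09 with absent unigenes at FPKM 0.3, -0.71 with the replicate block and -0.49, -0.52 and -0.01 without salt replicate 1, 2 or 3. DESeq2 called 860 higher and 976 lower, and limma on log2(FPKM + 0.1) 8 and 19. Settings chosen after seeing the data gave 6920 and 6570 (DESeq2 without salt replicate 3), 458 and 107 (DESeq2 on entries in 6 libraries) and 691 and 590 (unigenes in 5 libraries, mean count at least 50). The cause was not tested.

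The 565 and 636 entries called in 5 libraries became 1567 and 1425 with DESeq2, 289 and 289 summed per KO, 240 and 143 at a fold of at least 2, and 0 and 0 at an adjusted p under 0.01, with the batch term, with the replicate block or with all 6 libraries. Leaving out 1 library gave 0 to 2533 higher and 0 to 2120 lower. Without salt replicate 1, so salt replicate 2 alone, assumed to vary like the controls, it was 2533 and 2120, and without salt replicate 2 it was 293 and 318. Without control replicate 1, 2 or 3 it was 0 and 1, 0 and 0, and 0 and 0. All 565 and 636 kept their direction and an unadjusted p under 0.05 in those 3 fits, which share libraries. Fewer samples leave less power. The fits without a salt library hold as many libraries, but with 1 salt library left their spread comes from the controls alone. They therefore cannot show whether fewer samples account for the loss without a control. The cause of that loss was not tested. With a fold of at least 2, 0 in place of 6 terms were called. Whether replicate numbers pair the samples, as the replicate block assumes, stays open. Correlations of deviations for like numbers were 0.10, 0.06 and 0.02, each control's highest, a hint only. Salt deviations were taken from a mean that holds salt replicate 3, so these correlations cannot decide it. With that block all 565 and 636 kept their direction and an unadjusted p under 0.05, at median log2 differences of 0.90 and -0.78, against 0.90 and -0.76 without it.

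With all 6 libraries, named entries that turned were Jasmonate O-methyltransferase (0.27), Oxygen-evolving enhancer protein 3-1 (0.58), psaK (P36886, 0.061), Proline dehydrogenase 2 (0.47) and heat stress factor A-6a (0.36), on the log2 scale. For uncalled unigenes whose sign turned, values are those without salt replicate 3 (the first, also an end of the range with 1 library left out), with DESeq2 without it, and at the other end of that range. They were 0.017, 0.027 and -0.51 for Cluster-14027.153685 (cellulose synthase-like E6), 0.17, 0.17 and -0.76 for Cluster-14027.155730 (betaine aldehyde dehydrogenase 2), -0.12, -0.11 and 0.65 for Cluster-14027.156782 (Catalase-1), -0.30, -0.29 and 0.40 for Cluster-14027.158731 (Oxygen-evolving enhancer protein 1), -0.33, -0.32 and 0.80 for Cluster-14027.159225 (Phosphoenolpyruvate carboxylase 1), and -0.11, -0.10 and 0.77 for Cluster-14027.159664 (ETHYLENE INSENSITIVE 3). Cluster-14027.158734 (Heat shock protein 81-1) ranged from -0.024 without control replicate 3 to 0.065. Cluster-14027.160509 (SAG39) ranged from -0.68 to 0.010 without salt replicate 2, and was 0.26 with absent unigenes at FPKM 0.3 and 0.29 with upper quartile scaling.

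Of 13 lists called in 6 libraries and 7 in 5, 0 stayed with an estimated correlation and 0 with fry's test of 1 direction. With fry's mixed test, of change either way, the adjusted p was 0.00329 to 0.0255 in 5 libraries for the called lists except jasmonate (0.0664), and under 0.05 for the uncalled ones except dividing cells and ribosomal. In 6 libraries it was under 0.05 for aquaporin, epidermis, dehydrins, NAC and vascular (0.0271 to 0.0431). In 6 libraries the adjusted p with an estimated correlation and with fry was 0.578 and 0.875 (abscisic acid), 0.26 and 0.658 (aquaporin), 0.33 and 0.958 (cell wall), 0.0579 and 0.209 (epidermis), 0.0575 and 0.701 (ethylene), 0.107 and 0.185 (jasmonate), 0.0575 and 0.0678 (dehydrins), 0.0575 and 0.958 (NAC), 0.0575 and 0.117 (phenylpropanoid), 0.519 and 0.958 (senescence), 0.0925 and 0.958 (sugar osmolytes), 0.0579 and 0.875 (vascular), and 0.0579 and 0.117 (WRKY). Leaving out 1 library, chosen after seeing the data, gave 10 to 14 calls in 6 libraries and 5 to 9 in 5. The 10, without salt replicate 3, shared 5 of the 13 and added 5, and without salt replicate 1, 6 lists were called with an estimated correlation, against 0 without any other library. The adjusted p then ranged over 0.0285 to 0.18 (abscisic acid), 3.47e-13 to 0.0709 (aquaporin), 3.78e-08 to 0.445 (epidermis), 6.3e-05 to 0.25 (ethylene), 0.00022 to 0.18 (NAC), 0.016 to 0.745 (senescence), 0.00052 to 0.243 (sugar osmolytes) and 0.000517 to 0.747 (vascular), each highest without salt replicate 3. Lists not called in 6 libraries ranged over 2.22e-06 to 0.943 (Calvin cycle), 0.00586 to 0.943 (ion transport), 2.14e-08 to 0.995 (light reactions), 0.00548 to 0.943 (reference) and 0.0181 to 0.615 (ribosomal), each lowest without salt replicate 3. The light reactions list was called both ways, lower without salt replicate 3 and higher without salt replicate 2 (0.00269). Direction turned for light reactions (without control replicate 1 or 3 or salt replicate 3), Calvin cycle and reference (without salt replicate 2), ribosomal (without control replicate 3), and, without salt replicate 3, antioxidant (0.258 to 0.946), dividing cells (0.198 to 0.802) and proline and betaine (0.195 to 0.889). fry, which does not compare with other genes, turned the direction of abscisic acid and senescence, and of uncalled lists at 0.875 (antioxidant, ion transport, reference and ribosomal), 0.904 (phosphoenolpyruvate), 0.74 (dividing cells), 0.844 (heat shock) and 0.701 (light reactions). The non-plant CPM, salt minus control, was -9.48, and by group -13.8 for algae, oomycetes and other protists, 4.35 for animals and 0.0253 for fungi, with 77.2 for mites, 16.9 for aphids and 11.8 for lancelet by groups chosen after seeing the data.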

Other observations

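The tests of other splits and of few starting molecules were chosen after the result was seen, and those of length and of a stronger response before it. In the 5 libraries, laccases, which polymerise phenolic compounds such as lignin, were among the vascular entries that rose. These were singled out after their values were seen. Laccase-15 (Q339K6) stood at 40.6 CPM in controls and 115 in salts 1 and 2, and Laccase-7 (Q5N7B4) at 18.1 and 44.8 CPM. Potassium channel KAT1 (Q6K3T2), a channel of guard cells in Arabidopsis, stood at 24.9 and 96.8 CPM, with 7.27 CPM in salt replicate 3. Cation transporter HKT1 (Q0D9S3), a sodium transporter, stood at 60.8 and 36.1 CPM, and Phosphoenolpyruvate carboxylase kinase 2 (Q93VK0) at 103 and 21.9 CPM.

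For salt replicate 3, which stood apart from the other libraries, a small number of starting molecules could remove transcripts at random, but at a single rate the loss at 16 to 32 CPM predicts that 91.1% would be absent at 1 to 2 CPM, and 49.9% were. Absence did not rise steadily with length: at an FPKM of 4 to 8 in the other libraries, 34.9% of unigenes over 4000 nt and 37.4% of those of 500 to 1000 nt were absent, a ratio of 0.934. Unigenes of up to 500 nt were absent most often (53.6%, against 32.8% at 1000 to 2000 nt and 36.7% at 2000 to 4000 nt), but the mean unigene length weighted by counts was 1787 nt there and 2093 to 2235 nt in the others, so a lower yield of long transcripts among those present stays open. A stronger form of the response in salts 1 and 2 stays open, since across entries the ratio of salt replicate 3 to one control correlated at 0.266 to 0.295 with that of salts 1 and 2 to the other controls, between the bounds set. A different plant, tissue or label was not tested.

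With 10 splits of the libraries in each comparison, no share under 0.05 can be reached. For unigenes in 6 libraries, all 10 splits gave as many calls as the real one, which had 0, as did the highest other. At an unadjusted p under 0.05 the real split had 4977 and the highest other 1510. For entries in 5 libraries, 1 of the 10 splits, the real one, gave 1201 calls, and the highest other gave 0.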
